A study of Solanum lycopersicum with 6 samples.

How the data were processed

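Tomato roots of 20-day-old slszp1 mutant and wild type plants under 60 µM Al at pH 4.7 were measured by RNA sequencing, with 3 libraries per genotype that the labels call biological replicates. The authors deposited 1 table with a value per gene and library, and all 6 value columns were used. The header names no unit. The columns summed to 940694 to 974316 and held 2 decimals, so the deposited values were taken as TPM, a transcript abundance scaled to a fixed total per library. This is an inference from the values and not a statement of the authors. TopHat2, HISAT2, StringTie and Cufflinks are named per the submitters' processing notes, without versions or roles, and the genome build is not given in the sources used here. TPM keeps no sequencing depth, so absolute depth is unknown and no interval that needs it was given. A relative depth was estimated from the most common ratio between libraries of values from 0.1 to 1 TPM. With mutant replicate 3, the lowest, set to 1, it was highest at 1.44 in wild type replicate 2. This estimate was not checked against read counts.

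The table paired 35768 gene identifiers with descriptions, and all gene names come from it; 0 identifiers matched the RefSeq gene table at hand. Of these genes, 10620 were listed at 0 in all 6 libraries. Genes listed at 0 in a single library and at 10 TPM or more in all others numbered 0 to 4 per library, so an exact 0 can be a failed estimate. Such genes are given as values per library, with no fold change against a group at 0.

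Groups were taken from the labels. The design written before the data were examined assumed that counts might be held; the values were TPM, so the test for such values was used. Values were analysed as log2(TPM + 1), a scale that understates the change of low genes, for the 17702 genes at 1 TPM or more in at least 3 of 6 libraries. The mutant was compared with wild type by limma 3.58.1 (trend and robust options, with statmod 1.5.0) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. Replicate numbers were not used as a block.

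The 51 gene lists were patterns in the gene descriptions, fixed before the data were examined; 48 had at least 5 tested members. Lists were tested with limma's camera (preset correlation 0.01, and with an estimated correlation) and fry, each with Benjamini-Hochberg adjustment over lists. Counts of changed members were also adjusted over the list alone. The fixed pattern for aquaporins held 0 tested genes because the table uses other words for them. Lists for aquaporins under the name intrinsic proteins, both spellings of malate transporters, clock genes, CBF and DREB factors and ASR proteins were added after the data were seen. Their set tests were adjusted among the added lists only.

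Genes to be named were chosen by a rule fixed before the data were examined. It took changed STOP1 pathway and malate transporter genes, or the 3 most abundant if none changed. It took the 10 largest rises and 10 largest falls among changed genes without overlap between genotypes, an absence of overlap that chance gives 10% of the time for 3 against 3. It also took up to 3 changed members of each list with the smallest p, or the most abundant if none changed. The text gives a selection of those genes. The unchanged STOP1 pathway genes Solyc06g065440.1 and Solyc08g081110.2 and the root cap gene Solyc08g066590.3 were chosen after their values were seen. So were the malate transporter genes Solyc01g096140.3, Solyc08g082950.3 and Solyc11g071350.1, and the neighbours and ASR genes of the closing section.

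The alternatives fixed before the data were examined were a pseudocount of 0.1, no filter on low values, quantile normalization, the replicate number as a block, a change of at least 2-fold, each library left out in turn, and the other list tests. Centring each library on its median and leaving out gene models marked low quality or matched in part were added after the data were seen. The fit was tested on simulated values for 17702 genes, 17438 of which were tested. It recovered 55.6% of 99 genes changed by 1 on the log2 scale and 97% of 100 genes changed by 2, and 14 of 166 calls (8.43%) were false. In the simulation camera found the 1 shifted list and called 0 of 47 others. Noise was drawn independently for each gene, so false list calls from correlated genes could not appear. Far fewer genes were changed than were called in the data, so the recovered shares do not carry over to it.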

Results

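Roots of 20-day-old tomato (Solanum lycopersicum) plants kept in 60 µM aluminium (Al) solution at pH 4.7 were profiled by RNA sequencing, from 3 slszp1 mutant and 3 wild type samples described as biological replicates. SZP1 is known as a C2H2 zinc finger protein that interacts with STOP1 (SENSITIVE TO PROTON RHIZOTOXICITY 1), a zinc finger factor needed for Al and low-pH tolerance. The comparison asks which root transcripts differ under Al when SZP1 is mutated. The gene descriptions in the table do not name SZP1, so the targeted gene was not followed and the genotype labels were not checked against it. Roots without Al were not analysed here, so each difference is between genotypes under Al and not a response to Al. The deposited values are taken as TPM, and 17702 of 35768 listed genes reached 1 TPM in at least 3 libraries and were tested. The libraries held 17050 to 17728 genes at 1 TPM or more. Their absolute sequencing depth is unknown. Pearson correlations of log2(TPM + 1) across genes, which are not independent replicates, were 0.971 to 0.980 within the mutant, 0.952 to 0.974 within wild type and 0.877 to 0.916 between genotypes. Below, levels are means ± SD over n = 3 libraries, and changes are log2(TPM + 1) differences, mutant minus wild type, with their standard error (SE). The added 1 understates the change of low genes. A gene rose or fell where limma gave an adjusted p under 0.05.

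Most tested genes of the list for the Al tolerance pathway around STOP1 were lower in the mutant. Of the 6 tested genes that the list held, 4 fell and 0 rose by limma, with the same counts adjusted over the list alone and at an unadjusted p under 0.05. The gene described as aluminum sensitive 3 (ALS3, Solyc10g085950.2), which encodes an ABC-type transporter subunit required for Al tolerance in Arabidopsis, had 0.45 ± 0.236 TPM in the mutant and 76.9 ± 33.3 TPM in wild type. Its change was -5.65 (SE 0.35), with a limma adjusted p of 5.72e-05. Of 4 genes described as STOP1, 3 fell: Solyc11g017140.2 from 84.0 ± 4.36 TPM in wild type to 29.6 ± 3.28 TPM, Solyc04g056320.2 from 60.4 ± 4.45 to 13.8 ± 5.61 TPM, and Solyc11g066420.1, whose gene model is marked low quality, from 15.4 ± 5.11 to 1.62 ± 0.83 TPM. Their changes were -1.48 (SE 0.14), -2.13 (SE 0.28) and -2.64 (SE 0.31), with limma adjusted p of 0.000314, 0.00177 and 0.000768. In each of these 4 genes all 3 mutant libraries lay below all 3 wild type libraries. The other STOP1-described gene, Solyc06g065440.1, did not pass, at 13.1 ± 1.69 TPM in the mutant and 14.5 ± 5.24 TPM in wild type. Of the STOP1-described genes, it is the only one whose description gives a match to Arabidopsis STOP1. The remaining tested member, Solyc08g081110.2, described as aluminum induced, did not pass either, at 1.05 ± 0.0723 against 1.57 ± 0.609 TPM. The same 4 genes fell without any single library. Tested as a set against all other genes with limma's camera, the list was lower in the mutant (Benjamini-Hochberg adjusted p = 0.00239, and 0.00131 to 0.425 over the alternatives), the highest being the value with the correlation between genes estimated from these libraries.

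Aluminium-activated malate transporters (ALMT), a family with members that release malate that binds Al outside the root, did not pass where tested. Whether the tested genes are such members was not examined. The fixed list held 4 genes, and a list with both spellings of the name, added after the data were seen, held 23. In either list the same 2 genes reached the expression minimum. Solyc03g096820.3 had 8.5 ± 1.07 TPM in the mutant and 8.64 ± 2.13 TPM in wild type, and Solyc03g119640.3 had 2.79 ± 0.217 against 2.9 ± 0.878 TPM. Their changes were -0.003 (SE 0.209) and -0.02 (SE 0.222), with unadjusted limma p of 0.989 and 0.935, and both changes were positive under quantile normalization (0.034 and 0.035). Below the minimum, genes picked after their values were seen lay without overlap in both directions. Solyc01g096140.3 held 1.2, 0.52 and 2 TPM in the mutant and 0.36, 0.05 and 0.25 TPM in wild type. Solyc08g082950.3 was also higher, at 0.08, 0.04 and 0.03 TPM against 0 in every wild type library. Solyc11g071350.1 was lower, at 0.05, 0 and 0 TPM against 0.12, 0.09 and 0.34 TPM. Values this low are uncertain.

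**Figure D1:**
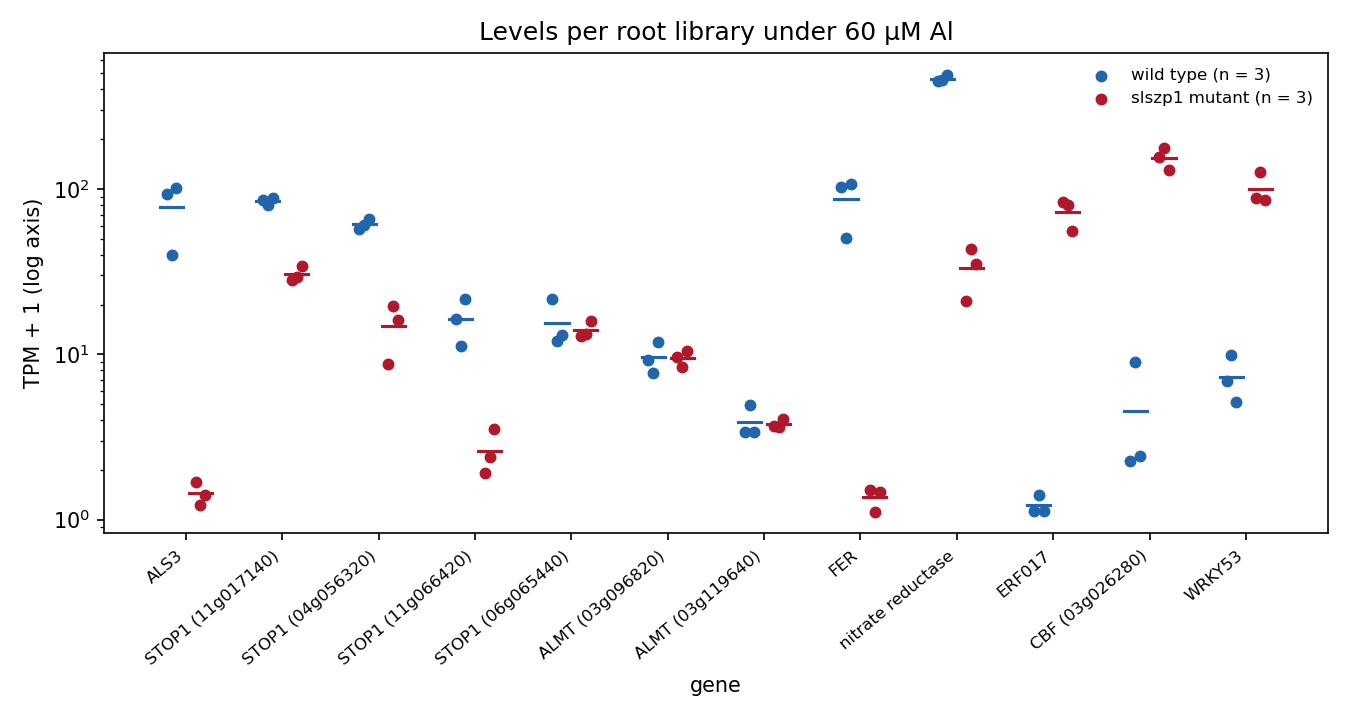
TPM + 1 on a log axis for 12 genes in each of 3 wild type (blue) and 3 slszp1 mutant (red) root libraries under Al, with a bar at the mean of each genotype. ALS3, 3 of 4 STOP1-described genes, FER and nitrate reductase lay lower in every mutant library than in any wild type library, the ALMT genes overlapped (their mean change was positive under quantile normalization), and ERF017, a CBF gene and WRKY53 lay higher.

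Across all tested genes, 3407 (19.2%) changed, of which 1542 were higher and 1865 lower in the mutant. The change was at least 2-fold for 911 of the higher and 1107 of the lower genes, and at least 8-fold for 92 and 90. The unadjusted p was under 0.05 for 5758 genes, and the median change of all tested genes was −0.0005. The count of changed genes was 2088 without wild type replicate 1, 2254 without mutant replicate 2 and 3885 without wild type replicate 2. The count of higher genes was 972 without wild type replicate 1 and 987 without mutant replicate 3, and that of lower genes 1116, 1196 and 1229 without wild type replicate 1, mutant replicate 2 and mutant replicate 1. Of 1315 genes that fell at least 2-fold in the fit without wild type replicate 2, that library lay below both other wild type libraries in 64.6%. The fit that chose these genes favours those high in the other wild type libraries. The share alone therefore does not show that wild type replicate 2 is unusual.

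**Figure D2:**
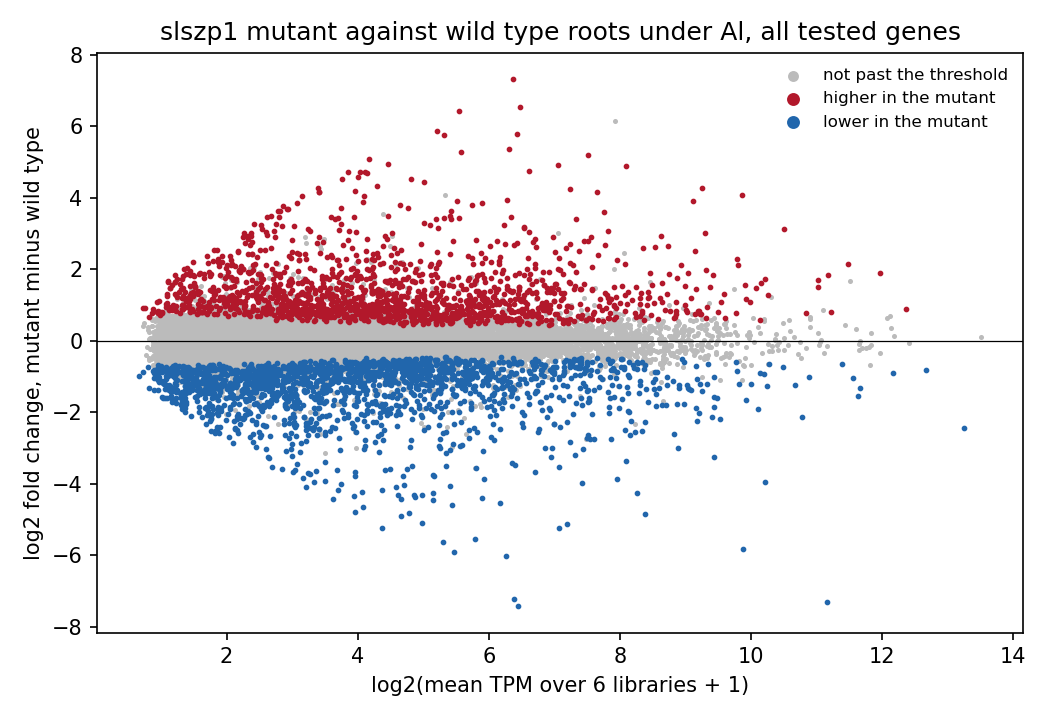
Change between genotypes (log2 fold change, mutant minus wild type) against mean level (log2 of mean TPM over 6 libraries + 1) for the 17702 tested genes, 1 point per gene. Red and blue points are the 1542 higher and 1865 lower genes, and grey points did not pass.

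Among the 10 named genes with the largest rise were 4 transcription factor genes, ERF017, 2 CBF genes and a MYB gene. ERF017 (Solyc12g009240.1), a member of the ethylene response factor family, had 72 ± 14.9 TPM in the mutant and 0.223 ± 0.162 TPM in wild type, a change of 5.88 (SE 0.21). CBF genes, named for factors that bind cold and dehydration response elements, rose at Solyc03g026280.3, with 153 ± 22.7 against 3.55 ± 3.8 TPM and a change of 5.38 (SE 0.53). At the CBF gene Solyc03g124110.2 the mutant libraries held 86.48, 88.07 and 57.07 TPM and the wild type libraries 0.51, 0.91 and 0 TPM (replicates 1, 2 and 3). The MYB gene Solyc06g005310.3 had 92.1 ± 37.8 against 1.32 ± 0.6 TPM and a change of 5.29 (SE 0.31). The limma adjusted p of these 4 genes were 7.41e-06, 0.00123, 1.61e-05 and 3.89e-05. A low-quality harbinger transposase-derived nuclease model (Solyc07g040960.1) rose from 10.1 ± 7.83 to 353 ± 58.7 TPM. A further 3 genes were listed at 0 in every wild type library. A 40S ribosomal S30-like gene (Solyc08g076335.1) held 172.77, 209.1 and 110.43 TPM in the mutant. The low-quality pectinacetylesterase model Solyc05g052560.1 held 58.33, 136.87 and 78.59 TPM. A partly matched chloroplastic 30S ribosomal protein S3 model (Solyc11g061710.1) held 36.43, 23.71 and 41.55 TPM. A hexosyltransferase gene (Solyc02g087350.2) held 176.73, 220.21 and 128.33 TPM in the mutant and 0, 0 and 5.29 TPM in wild type. A low-quality model for a nascent polypeptide-associated complex subunit (Solyc01g022780.1) held 93.21, 153.41 and 242.73 TPM and 0, 20.11 and 0 TPM. Its call was lost without any single library except wild type replicate 2 (limma adjusted p of 0.0889 to 0.115) and with a pseudocount of 0.1 (0.0917). Its limma adjusted p over all alternatives was 8.05e-05 to 0.115.

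The named genes with the largest fall included genes of iron uptake and auxin response besides ALS3. The gene described as fe inefficient (FER, Solyc06g051550.3), a bHLH factor required for iron uptake in tomato roots, had 0.373 ± 0.22 TPM in the mutant and 85.8 ± 31.8 TPM in wild type, a change of -5.92 (SE 0.30). SAUR38 (Solyc03g097510.1), one of the small auxin up-regulated RNA genes, had 1.43 ± 1.15 against 149.9 ± 34.7 TPM and a change of -6.03 (SE 0.33). ASR2 (Solyc04g071580.3), of the abscisic acid stress ripening family, fell from 4552 ± 1909 to 26.0 ± 5.59 TPM, a change of -7.31 (SE 0.35). A RING/U-box gene (Solyc04g009780.1) had 1.32 ± 0.402 against 107 ± 21.4 TPM, and a potyvirus VPg interacting protein gene (Solyc07g009280.3) 6.31 ± 3.53 against 262 ± 61.9 TPM. The limma adjusted p of these 5 genes were 2.47e-05, 3.71e-05, 3.04e-05, 7.59e-06 and 8.6e-05. A further 3 genes were listed at 0 in every mutant library. A serine-rich protein-related gene (Solyc07g007330.1) held 174.93, 168.06 and 172.04 TPM in wild type. ACI19 (Solyc02g065550.3) held 61.35, 25.7 and 31.11 TPM, and the low-quality maturase K model Solyc09g056390.1 held 77.53, 241.57 and 178.23 TPM. A gene model described as CBL-interacting protein kinase 23 (Solyc01g106630.2) held 18.16, 10.07 and 30.69 TPM in the mutant and 3641.52, 191.92 and 1786.93 TPM in wild type. The call was lost without mutant replicate 1, mutant replicate 2, wild type replicate 1 or wild type replicate 3 (limma adjusted p of 0.0876, 0.0933, 0.0640 and 0.0903; 0.000719 to 0.0933 over all alternatives). ASR2 lies in a cluster of genes of its family, and Solyc07g007330.1 and Solyc01g106630.2 lie beside genes with opposite or mirrored values. Reads can be divided among such neighbours, so these levels are uncertain.

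Genes of organic acid metabolism fell more often than they rose. In organic acid metabolism, 3 of 56 tested members rose and 13 fell (4 and 15 adjusted over the list alone). Glutamate dehydrogenase (Solyc10g078550.3), which links glutamate to 2-oxoglutarate, had 967 ± 202 TPM in the mutant and 2291 ± 366 TPM in wild type. Phosphoenolpyruvate carboxylase genes, which supply oxaloacetate for malate, fell at Solyc10g007290.3 with 6.7 ± 0.856 against 18.1 ± 1.31 TPM and at Solyc07g055060.3 with 2.87 ± 0.629 against 8.03 ± 1.09 TPM. That list did not pass limma's camera (Benjamini-Hochberg adjusted p = 0.0534, and 0.0143 to 0.495 over the alternatives). Among MATE family transporters, a family that includes citrate exporters, 4 of 40 tested members rose and 10 fell (5 and 10 adjusted over the list alone). Solyc12g005850.2 fell, with 16.5 ± 3.87 against 112 ± 13.1 TPM and a change of -2.71 (SE 0.19), and Solyc08g079730.1 rose, with 20.1 ± 3.18 against 4.67 ± 1.64 TPM. The MATE list did not pass limma's camera (Benjamini-Hochberg adjusted p = 0.142, and 0.495 with an estimated correlation). The lowest value over the alternatives came from fry, a different test, by which the MATE list was lower (adjusted p = 0.0181). Its balance turned without mutant replicate 2, where 6 rose and 5 fell; 4, 3 and 4 rose and 5, 5 and 6 fell without mutant replicates 1 and 3 and wild type replicate 3. Among proton pumps and genes of pH regulation, 2 of 36 tested members rose and 8 fell (2 and 13 adjusted over the list alone), with a plasma membrane H+-ATPase (Solyc03g034370.1) at 7.24 ± 3.3 against 31.2 ± 7.29 TPM. The list was lower by limma's camera (Benjamini-Hochberg adjusted p = 0.0272, and 0.0123 to 0.603 over the alternatives), and did not pass with an estimated correlation, without low-quality models (0.0801), without mutant replicate 3 (0.0709) or without wild type replicate 3 (0.0713). Its other leading members were carbonic anhydrases, Solyc02g067750.3 with 1.62 ± 0.619 against 54.5 ± 25.9 TPM and Solyc09g010970.3 with 5.52 ± 1.54 against 15.7 ± 1.52 TPM. These interconvert carbon dioxide and bicarbonate and pump no protons. Among ABC transporters, 2 of 74 tested members rose and 16 fell (5 and 17 adjusted over the list alone), led by Solyc06g068600.3 with 0.227 ± 0.11 against 23.7 ± 11.8 TPM. Without any single library but wild type replicate 2, 0 or 1 organic acid genes rose and 6 to 8 fell, and 1 or 2 proton pump and pH genes rose and 3 or 4 fell. Without mutant replicate 1 or 2, 9 ABC transporters fell, and 1 to 4 rose without single libraries.

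Most of the changed genes of phenylpropanoid synthesis and of wall proteins fell. In phenylpropanoid and lignin synthesis, 9 of 96 tested members rose and 32 fell (11 and 35 adjusted over the list alone). Phenylalanine ammonia-lyase, the entry enzyme of the pathway, fell at Solyc00g282510.2 with 2.24 ± 1.33 TPM in the mutant and 66.7 ± 8.3 TPM in wild type and at Solyc10g011920.2 with 0.937 ± 0.198 against 19.7 ± 3.34 TPM. A 4-coumarate:CoA ligase-like gene (Solyc03g025720.3) had 20.8 ± 4.86 against 644 ± 225 TPM. Among extensins and arabinogalactan proteins, structural glycoproteins of the wall, 2 of 49 tested members rose and 16 fell (2 and 21 adjusted over the list alone). Without low-quality or partly matched models, 2 of 32 rose and 8 fell. An extensin (Solyc04g071070.2) had 186 ± 40.3 against 645 ± 110.1 TPM. A fasciclin-like arabinogalactan protein gene (Solyc07g053540.1) rose, with 282 ± 47.5 against 49.7 ± 16.2 TPM. Among xyloglucan endotransglucosylases and expansins, which loosen the wall, 5 of 38 tested members rose and 12 fell (6 and 14 adjusted over the list alone). Expansin precursor 5 (Solyc02g088100.3) had 0.973 ± 0.741 against 8.75 ± 1.15 TPM and the expansin Solyc10g084780.2 0.227 ± 0.177 against 3 ± 0.211 TPM. In suberin and cutin synthesis, which marks exodermis and endodermis, 5 of 59 tested members rose and 12 fell (6 and 14 adjusted over the list alone). A fatty acyl-CoA reductase (Solyc11g067190.2) had 1.06 ± 0.338 against 28 ± 7.7 TPM and a feruloyl transferase (Solyc03g097500.3) 8.47 ± 3.73 against 74.3 ± 5.69 TPM. These 4 lists were lower by limma's camera, with Benjamini-Hochberg adjusted p of 0.00334, 0.00239, 0.0206 and 0.0303 in this order. With an estimated correlation their adjusted p from limma's camera were 0.495, 0.425, 0.495 and 0.495, the highest over all alternatives, and the lowest were 0.000709, 0.000441, 0.00651 and 0.0145. Without wild type replicate 2, limma's camera did not pass wall loosening (adjusted p = 0.200) or suberin and cutin (adjusted p = 0.0537), and without mutant replicate 3 it did not pass phenylpropanoids (adjusted p = 0.0709) or suberin and cutin (adjusted p = 0.0547). In the same libraries, of 142 histone and cell cycle genes, a list meant for dividing cells, 7 rose and 17 fell (5 and 17 adjusted over the list alone). By limma's camera the adjusted p was 0.0303, and 0.00428 to 0.495 over the alternatives. The falls with the smallest p were of genes described as cyclin-dependent kinase inhibitors, which are not markers of division. Solyc11g066000.1 had 0.417 ± 0.0902 against 4.85 ± 1.19 TPM and Solyc02g067810.1 5.83 ± 1.22 against 22.9 ± 6.1 TPM. The list was not tested without such inhibitors, so the counts do not decide whether there were fewer dividing cells. A histone H4 gene (Solyc06g005430.1) had 52.4 ± 13.3 against 119 ± 15.2 TPM. That list did not pass limma's camera with an estimated correlation (adjusted p = 0.495), without mutant replicate 3 (adjusted p = 0.123) or without wild type replicate 2 (adjusted p = 0.295), nor did it pass fry (adjusted p = 0.0677). Of its genes 5, 10, 6 and 10 fell and 5, 4, 4 and 4 rose without mutant replicates 2 and 3 and wild type replicates 1 and 3. Of the wall loosening genes 2, 0, 2 and 1 rose without those same libraries, and 3, 3 and 2 suberin and cutin genes rose without mutant replicates 1, 2 and 3.

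Other wall and oxidative stress lists held changed genes in both directions. In pectin modification, 8 of 57 tested members rose and 11 fell (12 and 13 adjusted over the list alone), with 10 and 10 under quantile normalization. A pectin methylesterase inhibitor family gene (Solyc03g083730.1) rose to 732 ± 58.5 from 116 ± 11.4 TPM. In cellulose and callose synthesis, 8 of 44 tested members rose and 7 fell (8 and 7 adjusted over the list alone). Among class III peroxidases, 8 of 74 tested members rose and 15 fell (10 and 20 adjusted over the list alone), with Solyc05g050890.2 at 5.37 ± 0.0361 against 73.9 ± 24.1 TPM and Solyc04g071900.3 at 8.8 ± 0.803 against 1.29 ± 0.57 TPM. Among antioxidant and detoxification enzymes, 18 of 180 tested members rose and 31 fell (19 and 34 adjusted over the list alone), with a glutathione S-transferase-like gene (Solyc07g056470.3) at 79.5 ± 15.5 against 462 ± 139 TPM and a thioredoxin gene (Solyc04g081970.3) at 23.3 ± 1.34 against 5.77 ± 0.864 TPM. In flavonoid synthesis, 1 of 17 tested members rose and 5 fell (1 and 6 adjusted over the list alone), and 3 rose without mutant replicate 1. Without mutant replicate 3, 5 pectin genes rose. Cellulose and callose genes turned to fewer higher than lower without mutant replicate 2 (5 and 6), mutant replicate 3 (4 and 5) and wild type replicate 1 (3 and 5), with 7 and 4 without wild type replicate 3. Antioxidant and detoxification genes numbered 11 to 13 higher and 19 to 22 lower without any mutant library or wild type replicate 1.

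Genes for nutrient uptake and assimilation included some of the larger falls. In nitrogen transport and assimilation, 3 of 23 tested members rose and 7 fell (3 and 7 adjusted over the list alone). Nitrate reductase (Solyc11g013810.2), which reduces nitrate to nitrite, had 32.2 ± 11.4 TPM in the mutant and 464 ± 22.3 TPM in wild type, a change of -3.87 (SE 0.25). A high-affinity nitrate transporter (Solyc06g074990.2) had 1.3 ± 0.556 against 27.9 ± 4.04 TPM and a glutamine synthetase (Solyc11g011380.2) 114 ± 20.6 against 551 ± 54.4 TPM. In sulfur assimilation and transport, 2 of 23 tested members rose and 7 fell (4 and 7 adjusted over the list alone). Sulfite reductase (Solyc11g065620.2) had 14.1 ± 1.07 against 62.2 ± 7.96 TPM, and adenylylsulfate reductase genes fell at Solyc02g032860.3 with 14.4 ± 4 against 41.7 ± 3.99 TPM and at Solyc02g080640.3 with 11.9 ± 2.33 against 36.4 ± 10.3 TPM. In the phosphate starvation list, 3 of 38 tested members rose and 7 fell (3 and 10 adjusted over the list alone). A purple acid phosphatase gene (Solyc07g008550.3) rose, with 79.8 ± 7.87 against 29.7 ± 2.86 TPM, and another (Solyc07g008570.3) fell, listed at 0, 0 and 0.09 TPM in the mutant and 3.81, 3.56 and 8.13 TPM in wild type. That list was lower by limma's camera (Benjamini-Hochberg adjusted p = 0.0303, and 0.0231 to 0.495 over the alternatives), and did not pass with an estimated correlation, without a filter on low values (0.0616), without low-quality models (0.0770) or without mutant replicate 3 (0.0709). In iron homeostasis, 4 of 27 tested members rose and 4 fell (4 and 7 adjusted over the list alone). FER, which fell, is described only as fe inefficient and is not in these counts. A vacuolar iron transporter family gene (Solyc01g104780.3) held 0.15, 0 and 0.36 TPM in the mutant and 16.6, 11.32 and 13.92 TPM in wild type. Ferritin (Solyc06g050980.3), the iron storage protein, had 21.3 ± 7.72 against 71.4 ± 11.7 TPM, and a metal transporter gene (Solyc02g092800.3) rose with 57.9 ± 7.09 against 19.1 ± 4.08 TPM. In potassium transport, 5 of 22 tested members rose and 1 fell (6 and 1 adjusted over the list alone). The channel TORK1 (Solyc05g051220.3) rose, with 12.6 ± 2.31 against 4.87 ± 1.64 TPM. The 1 that fell was the partly matched CBL-interacting protein kinase 23 model Solyc01g106630.2, whose level is uncertain as given above. In this list, 3, 1 and 2 genes rose without mutant replicate 3, wild type replicate 1 and wild type replicate 3, and 0 to 2 fell without single libraries. In sugar transport, 9 of 48 tested members rose and 10 fell (11 and 13 adjusted over the list alone), and the bidirectional SWEET transporter genes Solyc06g060590.3 and Solyc03g097610.3 rose, with 60.7 ± 15.6 against 1.81 ± 0.486 TPM and 30.7 ± 9.66 against 1.24 ± 0.985 TPM. The sugar transport balance turned to 7 higher and 3 lower without mutant replicate 1 or wild type replicate 1, 8 and 5 without mutant replicate 2, and 9 and 5 without wild type replicate 3. Phosphate genes turned to 3 higher and 2 lower without mutant replicate 1 and 2 and 1 without mutant replicate 2, and 2 rose and 3 or 4 fell without mutant replicate 3, wild type replicate 1 or wild type replicate 3. Without any single library but wild type replicate 2, 3 or 4 sulfur genes fell. Without mutant replicate 2 or wild type replicate 1, 4 nitrogen genes fell, and 2 iron genes rose without mutant replicate 3, wild type replicate 1 or wild type replicate 3.

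Among transcription factor families, most of the changed WRKY genes rose. Of 59 tested, 13 rose and 2 fell, with the same counts adjusted over the list alone. WRKY53 (Solyc08g008280.3) had 99.3 ± 22.2 TPM in the mutant and 6.31 ± 2.4 TPM in wild type, a change of 3.81 (SE 0.26). WRKY46 (Solyc08g067340.3) had 181 ± 37.1 against 28.8 ± 5.61 TPM, whereas WRKY71 (Solyc02g071130.3) fell, with 16.8 ± 0.851 against 52.5 ± 2.13 TPM. The family was higher by limma's camera (Benjamini-Hochberg adjusted p = 0.0178, and 0.00531 to 0.425 over the alternatives), and did not pass with an estimated correlation; 11 to 14 rose without single libraries. Among ethylene synthesis and response genes, 22 of 118 tested members rose and 16 fell (25 and 20 adjusted over the list alone), with ERF5 (Solyc03g093540.1) at 36.3 ± 7.31 against 0.84 ± 0.229 TPM besides ERF017. Among MYB factors, 22 of 108 tested members rose and 15 fell (24 and 16 adjusted over the list alone). Among NAC factors, 8 of 53 tested members rose and 4 fell (8 and 4 adjusted over the list alone), with the low-quality model of NAC35 (Solyc03g044560.1) lower at 2.23 ± 0.214 against 38.5 ± 2.38 TPM. Among bHLH factors, 13 of 99 tested members rose and 13 fell (14 and 15 adjusted over the list alone), a count that leaves out FER for its description. The gene bHLH068 (Solyc10g079680.2) was listed at 0 in every wild type library and at 12.14, 13.16 and 12.44 TPM in the mutant. Among genes described as C2H2 zinc finger proteins, 3 of 21 tested members rose and 1 fell (3 and 1 adjusted over the list alone). In this list Solyc06g075780.2 had 171 ± 46.8 against 56.3 ± 8.49 TPM. STOP1 belongs to the same family, but the STOP1-described genes, 3 of which fell, lack the term in their descriptions. They are not in these counts. Among F-box proteins, 26 of 278 tested members rose and 15 fell (21 and 10 adjusted over the list alone), with an F-box/LRR gene (Solyc10g076290.2) at 4.37 ± 1.12 against 113 ± 31.3 TPM. Of the F-box genes, 16, 16, 16 and 17 rose without mutant replicates 1, 2 and 3 and wild type replicate 3, and 5, 7, 7 and 8 fell without mutant replicates 1 and 2 and wild type replicates 1 and 3. Without mutant replicate 3, 10 ethylene genes fell, 5 NAC genes rose and 2 fell, and 8 bHLH genes rose, as they did without mutant replicate 2. The count of lower C2H2 genes was 2 without wild type replicate 2 and 0 without any other library. In the same libraries 21 clock genes had a median change of 0.41, with 4 higher and 1 lower (2 and 1 of 15 without low-quality or partly matched models). This list was added after the data were seen and includes genes described as cold regulated 27.

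Signalling and hormone lists held changes both ways. Among receptor-like kinases, 39 of 217 tested members rose and 16 fell (40 and 23 adjusted over the list alone), and 24 rose without mutant replicate 1, mutant replicate 2 or wild type replicate 1. Without these and wild type replicate 3, 5 to 7 receptor-like kinases fell. In calcium signalling, 18 of 132 tested members rose and 14 fell (20 and 14 adjusted over the list alone), with 7 to 9 lower without any library but wild type replicate 2. Among auxin genes, 13 of 109 tested members rose and 22 fell (13 and 23 adjusted over the list alone), with SAUR36 (Solyc03g082520.1) at 143 ± 31.3 against 2233 ± 523 TPM and an auxin repressed gene (Solyc02g077880.3) at 1465 ± 166 against 298 ± 23.2 TPM. Without wild type replicate 1, 8 auxin genes rose and 12 fell. Among jasmonate genes, 6 of 36 tested members rose and 7 fell (8 and 10 adjusted over the list alone). The jasmonate counts were 1 and 4, 6 and 4, and 4 and 4 without mutant replicates 1, 2 and 3, and 0 and 3, and 3 and 3 without wild type replicates 1 and 3. Among abscisic acid and dehydration genes, 9 of 79 tested members rose and 16 fell (9 and 19 adjusted over the list alone), with a dehydrin (Solyc02g062390.3) lower at 7.46 ± 1.55 against 66.7 ± 13.9 TPM and the late embryogenesis gene Lea5 (Solyc09g075210.3) higher at 3638 ± 659.8 against 1009.9 ± 175 TPM. Without low-quality or partly matched models, 8 of 54 of these genes rose and 9 fell. Among gibberellin, cytokinin and brassinosteroid genes, 3 of 42 tested members rose and 8 fell (4 and 10 adjusted over the list alone), with 5 higher without wild type replicate 2 and 3 or 4 lower without any other library. Of 20 polyamine genes, 0 rose and 6 fell by limma (0 and 7 adjusted over the list alone, and 3 and 7 at an unadjusted p under 0.05). Among the lower ones was arginine decarboxylase 1 (Solyc10g054440.2), a first step towards putrescine, at 251 ± 46.9 against 587 ± 82.2 TPM. Among pathogenesis-related proteins and chitinases, 17 of 107 tested members rose and 20 fell (19 and 25 adjusted over the list alone), with 17 and 15 without wild type replicate 3. Among proteinase inhibitors, 5 of 39 tested members rose and 8 fell (5 and 10 adjusted over the list alone). Among cytochrome P450 genes, 22 of 146 tested members rose and 33 fell (29 and 39 adjusted over the list alone). The P450 counts were 15 and 20, 15 and 18, 15 and 20, and 19 and 16 without mutant replicates 1 and 2 and wild type replicates 1 and 3. The UDP-glycosyltransferase list had 1 higher and 2 lower of 19 (1 and 2 adjusted over the list alone), and in terpenoid and steroidal alkaloid synthesis 3 of 21 tested members rose and 6 fell (3 and 7 adjusted over the list alone). Without single libraries 1 or 2 glycosyltransferase genes rose and 0 to 2 fell, and the terpenoid counts were 1 and 3, 1 and 2, and 1 and 4 without mutant replicate 3 and wild type replicates 1 and 3. Among ubiquitin and proteasome genes, 21 of 313 tested members rose and 30 fell (17 and 27 adjusted over the list alone). Without any library but wild type replicate 2, 11 or 12 of these rose, and 13 to 15 fell without mutant replicate 1, mutant replicate 2 or wild type replicate 1.

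Lists for other tissues and for RNA quality gave these counts. Of 51 green tissue genes, 5 rose and 6 fell, and photosystem I subunit VI (Solyc03g120640.3) had 118 ± 11.5 against 35.2 ± 8.77 TPM. Among Casparian strip genes of the endodermis, 5 rose and 6 fell of 37, with the CASP-like gene Solyc02g078250.3 at 3.25 ± 0.104 against 51.8 ± 23.7 TPM. Of 22 genes in the root hair list, 1 rose and 0 fell by limma (3 higher and 1 lower at an unadjusted p under 0.05). The 1 that rose was an ethylene-forming enzyme gene (Solyc12g098850.2), at 319 ± 74.3 against 44.8 ± 7.18 TPM. It entered the list because the letters of forming match the term formin, so its rise does not speak for root hairs. In xylem, 2 rose and 4 fell of 21, and in phloem 4 rose and 4 fell of 14. Of 2 tested root cap genes 0 changed by limma, and 1 (Solyc08g066590.3) had an unadjusted limma p under 0.05 (0.0426). Of 113 heat shock and chaperone genes, 4 rose and 18 fell, with an HSP90 gene (Solyc04g081630.2) at 0.203 ± 0.214 against 31.6 ± 15.6 TPM; 11 fell without mutant replicate 1, mutant replicate 2 or wild type replicate 1. Of 278 cytosolic ribosomal protein genes, 6 rose and 8 fell. Adjusted over each list alone, the higher and lower counts of these 8 lists were 5 and 6, 5 and 7, 1 and 0, 2 and 7, 4 and 4, 0 and 0, 4 and 18, and 2 and 2. Small counts here moved with single libraries. The green tissue counts were 5 and 3 without mutant replicate 2 and 5 and 2 without wild type replicate 1, and turned to 8 and 6 under quantile normalization. Casparian strip genes turned to 3 higher and 2 lower without mutant replicate 1 or wild type replicate 1, and 3 rose and 4 fell without mutant replicate 2 or 3. Without mutant replicate 1, mutant replicate 2 or wild type replicate 1, 2 xylem genes fell, and 1 or 2 phloem genes rose and 1 or 2 fell without any library but wild type replicate 2. Without wild type replicate 2, 1 root hair gene fell and 9 heat shock genes rose; 2 heat shock genes rose without any mutant library or wild type replicate 1, and without low-quality or partly matched models 3 of 90 rose and 9 fell. Ribosomal protein counts were 4 and 4, 3 and 4, 4 and 5, and 3 and 2 without mutant replicates 1, 2 and 3 and wild type replicate 1.

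**Figure D3:**
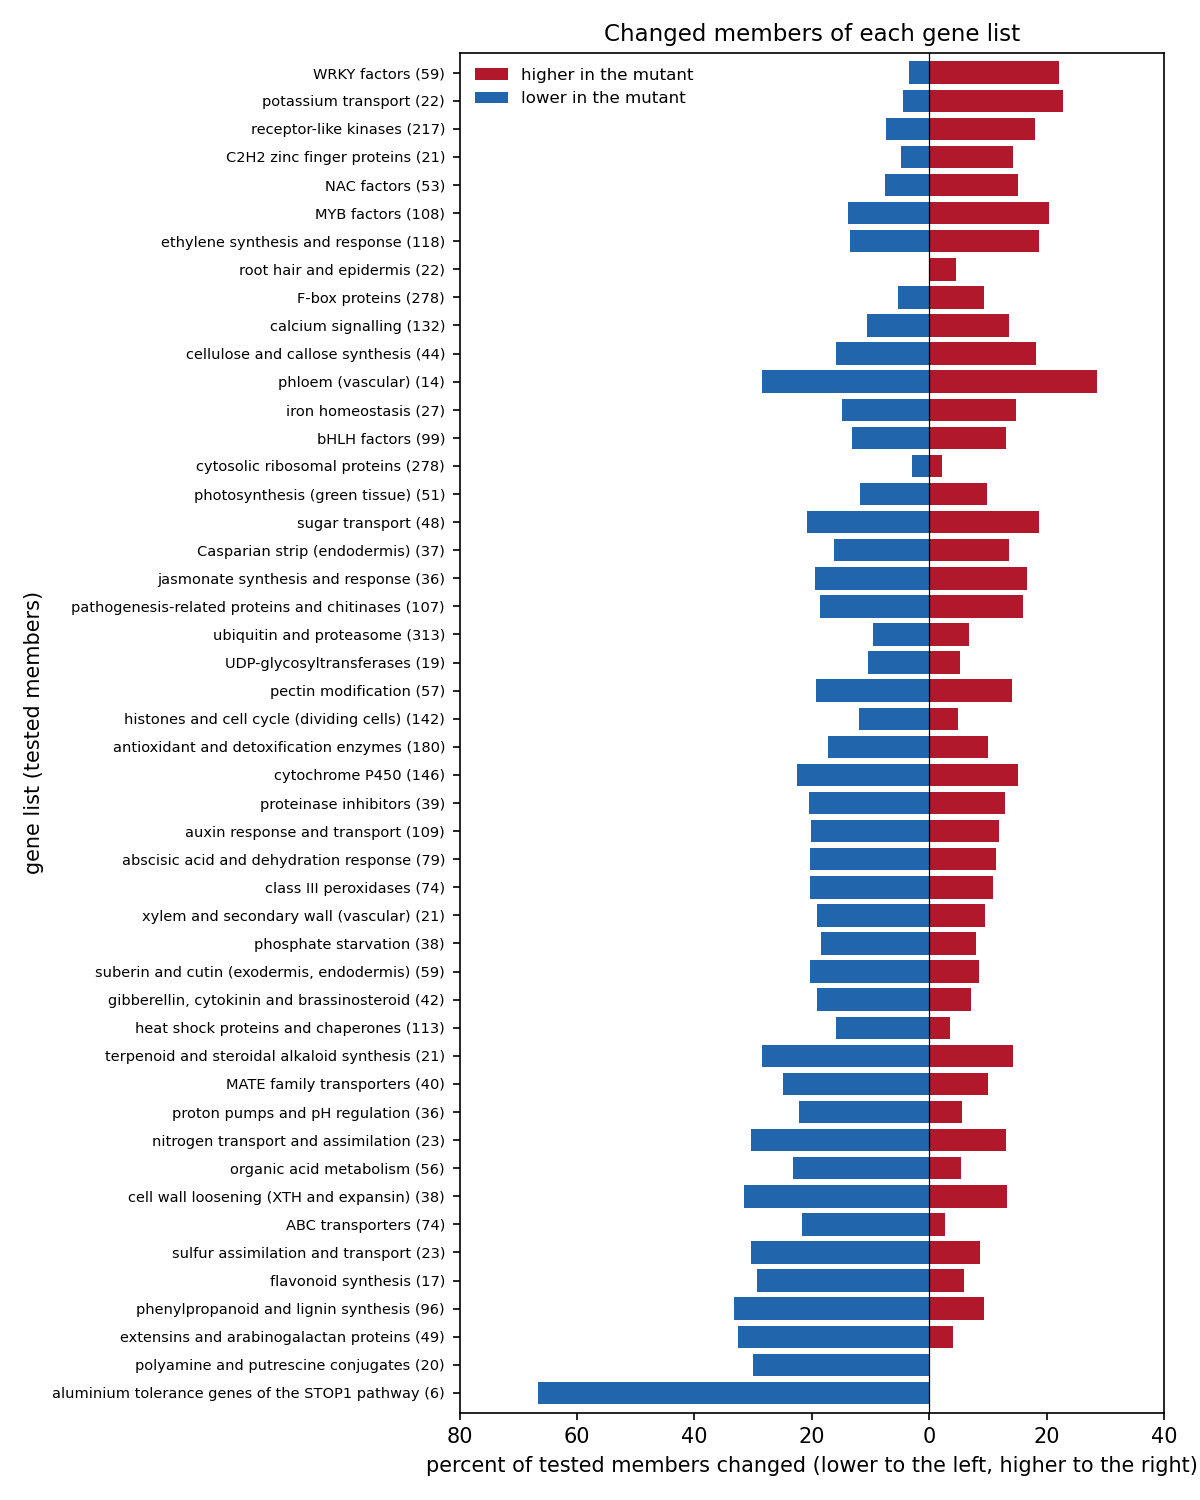
Percent of tested members that fell (blue, left) or rose (red, right) in the slszp1 mutant, with the number of tested members in brackets. Shown are the 48 gene lists fixed before the data were examined that had 5 or more tested genes. Lists added later are not shown. Among these lists, the STOP1 pathway list, with 4 of 6 members lower, reaches farthest to the left. WRKY factors, with 13 higher and 2 lower of 59, stand at the top of them.

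By limma's camera with a preset correlation, 9 of the 48 lists with 5 or more tested members passed, 1 higher and 8 lower, and 0 passed with an estimated correlation (smallest adjusted p = 0.425). By fry, which asks whether a list's own genes moved on balance in 1 direction, 21 passed, 2 higher and 19 lower, and for change in either direction 48 passed. The 2 higher lists were WRKY factors and ethylene genes. Among the lower were antioxidant and detoxification enzymes, flavonoid synthesis and class III peroxidases (fry adjusted p = 0.00472, 0.0140 and 0.0181). Median and mean change differed in sign in 5 lists, which were nitrogen, C2H2, sugar transport, jasmonate and ribosomal protein genes, and for bHLH factors camera's direction (higher) differed from both.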

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

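Median centring, leaving out low-quality or partly matched gene models, and the member counts of lists without each library were chosen after the result was seen. ALS3 and 3 STOP1-described genes fell in every alternative that tested them. Of 3407 changed genes, 3260 were also called with a pseudocount of 0.1, 2790 without a filter on low values, 3234 with quantile normalization and 3250 with median centring. A change of at least 2-fold left 2018 genes, 911 higher and 1107 lower, by its construction.

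Without single libraries the changed genes numbered 2088 to 3885, with 972 to 1765 higher and 1116 to 2120 lower. The fewest were called without wild type replicate 1 and the most without wild type replicate 2; 2254 were called without mutant replicate 2. Fewer samples lower the count in general, and the cause of the rise without wild type replicate 2 was weighed only for mixed RNA. The lists passing limma's camera numbered 4 without mutant replicate 3 to 11 without mutant replicate 1, against 9 with all libraries. They numbered 0 with an estimated correlation, and 21 by fry, 8 of them shared with camera; fry asks another question, and the cause for the estimated correlation was not tested.

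The malate transporter changes reversed in sign, being close to 0: Solyc03g096820.3 was 0.034 with quantile normalization and -0.15 to 0.16 without single libraries, and Solyc03g119640.3 was 0.035 and -0.11 to 0.16. The root cap gene Solyc07g063490.3 ranged from -0.39 to 0.36 without single libraries. None of these 3 genes passed in any of those fits, and the cause was not tested. Of 159 named genes, the calls ended for 1 with a pseudocount of 0.1, for 1 with the replicate block, and for 0 to 7 without single libraries.

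With the replicate number as a replicate block, 2775 genes changed, 2638 of them among the 3407, and 10 lists passed limma's camera, including the same 9. Deviations from the group means correlated at -0.05, -0.07 and 0.11 between libraries of the same number, and mutant replicate 2 correlated best with wild type replicate 1 (0.14), so the numbers were not treated as pairs. Count-based alternatives planned before the data were examined (other size factors, count filters and count models) were not run because the table holds no counts. Unknown absolute depth limits what can be said of genes near 1 TPM.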

Other observations

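The test of neighbouring gene models, the share of lower genes with wild type replicate 2 below both others, the summed neighbour values and the lists of aquaporins, clock genes, CBF and DREB factors and ASR proteins were chosen after the result was seen.

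Aquaporins, channels for water and small solutes, fell more often than they rose. Of 31 tested, 3 rose and 11 fell (5 and 13 adjusted over the list alone), and 9 or 10 fell without single libraries. NIP1.1 (Solyc03g005980.3) had 0.653 ± 0.429 TPM in the mutant and 47.9 ± 1.29 TPM in wild type. PIP2.10 (Solyc09g007760.3) had 7.7 ± 0.51 against 66.1 ± 4.59 TPM and TIP2.3 (Solyc06g060760.3) 19 ± 4.06 against 321 ± 85.5 TPM, while NIP2.1 (Solyc03g013340.3) rose, with 22.7 ± 8.03 against 1.76 ± 1.05 TPM. The most abundant aquaporins had higher means in the mutant without passing. TIP2.1 (Solyc12g044330.2) had 1230 ± 363 against 483 ± 269 TPM (limma adjusted p = 0.0517) and PIP2.6 (Solyc11g069430.2) 858 ± 260 against 534 ± 37.1 TPM (0.0993). TIP1.3 (Solyc10g083880.2) had 873 ± 289 against 438 ± 206 TPM (0.116). The counts therefore do not show that aquaporin transcript as a whole was lower. By limma's camera the list was lower (adjusted p = 0.012 over the added lists only, and 0.469 with an estimated correlation). All 4 changed genes of 5 tested CBF and DREB factors rose, with a median change of 2.55 over the list. By limma's camera its adjusted p was 0.000803 over the added lists only, and 0.218 with an estimated correlation. The list was added after the data were seen and holds the 2 CBF genes named among the largest rises. Its set test therefore restates those rises and adds no support.

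Of 6 ASR genes, 3 rose and 2 fell, with 1 lower without any library but wild type replicate 2. ASR2 fell, while ASR1 (Solyc04g071610.3) had 839 ± 20.7 against 445 ± 128 TPM and 2 genes described as ASR4 had 378 ± 127 against 22.4 ± 15.8 TPM (Solyc04g071615.1) and 292 ± 93.9 against 27.7 ± 12.6 TPM (Solyc04g071620.3). Summed over the 6 genes, the level was 3699 ± 352 TPM in the mutant and 7905 ± 2329 TPM in wild type. These genes form a cluster of 1 family whose sequences were not compared here, so the split of reads among them is uncertain.

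A set of 13 genes was listed at 0 in all 3 libraries of 1 genotype and at 10 TPM or more in all 3 of the other, 8 present in the mutant and 5 in wild type, on 10 chromosomes. Among them were the 40S ribosomal S30-like gene (Solyc08g076335.1) and the serine-rich gene (Solyc07g007330.1). Of these genes 61.5% (exact 95% interval 31.6% to 86.1%) carried a low-quality or partial-match mark, against 14.4% of the 9815 genes at 10 TPM or more (Fisher's exact test, two-sided p = 0.000118), so doubtful gene models may account for part of the set. For linked genome segments that differ between the lines, 0% of them had another such gene within 10 places. That cannot be told apart from chance, because the median of 1000 random draws was also 0%, their 95th percentile was 15.4%, and 0 of 13 allows up to 24.7%. For reads assigned between neighbouring gene models, 23.1% (3 of 13) had a gene within 2 places called in the opposite direction, against a median of 15.4% and a 95th percentile of 38.5% in random draws. This too cannot be told apart, since 3 of 13 allows up to 53.8%. For single pairs, the neighbour Solyc07g007325.1 of the serine-rich gene had 214 ± 41.5 TPM in the mutant and 51.9 ± 7.92 TPM in wild type, and both summed gave 214 ± 41.5 and 224 ± 4.79 TPM. PR1 (Solyc01g106620.2) held 303.31, 2872.43 and 2263.98 TPM in wild type where the CIPK23 model (Solyc01g106630.2) held 3641.52, 191.92 and 1786.93 TPM, and their sums were 4043 ± 682 and 3687 ± 542 TPM in mutant and wild type. A genotype effect on these genes stays open as untested.

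ERF017, ERF5, 2 CBF genes and WRKY53, put together after their values were seen, were higher in the mutant, while WRKY71 and NAC35 fell. The ethylene list held changes both ways (22 higher and 16 lower of 118), and was higher on balance by fry (adjusted p = 0.0115). For the 5 higher genes a different time of day at harvest could contribute: 21 clock genes had a median absolute change of 0.491, against a median of 0.302 and a 95th percentile of 0.479 in 10000 random lists matched on mean level. That places the list at percentile 95.79, close to the limit set. It includes genes described as cold regulated 27, among them its largest change (Solyc03g026000.3, 2.77) and the gene at its median (Solyc10g050220.2, -0.491). The list is therefore not independent of a cold-type response, and the test cannot decide on harvest time. The labels give no harvest time, and an effect of the genotype on these genes stays open as untested.

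Wild type replicate 2 lay between the other wild type libraries and the mutant at many lower genes. Over 1315 such genes it stood 38.1% (35.5% to 40.8%) of the way to the mutant level, against 10.01% over 1076 higher genes. Both sets came from a fit without that library, which favours genes where the other wild type libraries lie far from the mutant. A held-out library is then likely to lie nearer the mutant. No like share was taken for wild type replicate 1 or 3, so these shares do not show that replicate 2 is unusual. The interval resamples genes and not libraries. Mutant RNA mixed into wild type replicate 2 would raise certain genes by a like share. These are at 0 in the other wild type libraries and at 10 TPM or more in every mutant library. The median share at 15 such genes was 0% (bootstrap interval 0% to 15.6%), which lies below the share needed. Of the 15, 8 were at 0 in wild type replicate 2. These are the 8 genes given above as present only in the mutant, 5 of which carry a low-quality or partial-match mark. An exact 0 can be a failed estimate. The 15 genes therefore argue against mixed RNA at the share needed only as far as these zeros hold. Mixing would also move the 1076 higher genes by a like share. Their 10.01%, given without an interval, lies below the share needed and does not rest on these zeros. Neither value excludes a smaller share. Natural variation between root samples stays open as untested.

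Of the 10 splits of the 6 libraries into 3 and 3, the real one called 3407 genes and the highest of the others 1; 10 splits are too few for a share under 0.05. For the lists passing camera, the real split called 9 and the highest other 16, and 3 of 10 splits called as many, so chance cannot be excluded for the number of lists.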
